A study of Drosophila melanogaster with 8 samples.

How the data were processed

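Total RNA of Drosophila melanogaster larvae of the last instar was measured on 8 spotted cDNA arrays read in 2 colours. On 4 arrays the Rover background was used and on 4 the sitter background. Per the labels, channel 1 of each array held RNA of control larvae of that background and channel 2 held RNA of larvae of the same background carrying DGCalpha1[3], a mutant allele of the gene now named Gycalpha99B. Each direct labelling used 80 µg of RNA. The labels do not state whether the arrays came from separate larvae or separate extracts, so every p-value measures only the spread between these arrays, which may be technical.

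Per the labels, the slides were scanned on a ScanArray 4000 and quantified with QuantArray version 3 by its adaptive method, with no background subtraction. Replicate 1 of each background was of print lot A and was hybridised for 15.75 hours, and replicates 2 to 4 were of print lot B and were hybridised for 17.75 hours. The gain of the Cy5 detector was 64 on 5 arrays and 67 or 68 on 3. The deposited values are 1 ratio per spot and array, made by the authors from normalised intensities, and the normalisation method is not given in the sources used here. The values run below 0 and reach 10.7, and they were taken as deposited log2 ratios. Base 2 is an assumption, as the log base is not stated. The dye of each channel, any exchange of dyes between arrays and the channel in the numerator are not given either. For this reason a ratio is called positive or negative throughout, and it is not read as higher or lower in the mutant. No array pair had a correlation below 0 across features, the lowest being 0.312 between backgrounds, and no array's sign was turned. Probe and print effects common to all arrays also give positive correlations, so this check does not exclude an array with exchanged dyes.

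The table held 27648 spots on each of the 8 arrays with 0 missing values. A probe table listed 15218 spots, of which 15116 had 1 gene symbol and 102 had several. The remaining 12430 spots were not listed and are unnamed here. Gene IDs of 14894 named spots matched the Release 6 gene table, 222 did not, and 0 symbols changed. Spots of the same gene were averaged per array, which gave 6793 genes, 6106 of them from 2 spots and 687 from 4 or more. All other spots were kept by themselves, 12532 in number, for 19325 tested features. In each of 7609 neighbouring pairs of named spots both spots held the same gene, so unnamed neighbours are probably duplicate spots too and are counted separately.

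Ratios were fitted with limma 3.58.1 in R 4.3.3, with a mean for each background over all 8 arrays (6 residual degrees of freedom) and empirical Bayes moderation. The 4 comparisons were the Rover mean against 0, the sitter mean against 0, the mean of both against 0, and Rover minus sitter. P-values were adjusted by Benjamini-Hochberg over all 19325 features and called under 0.05. Adjusted p-values in the text come from this limma fit unless another test is named. For 21 gene lists, camera was run on the 6793 genes with an inter-gene correlation of 0.01, with a correlation estimated for each list as an alternative. The test fry was run beside it; it asks whether the genes of a list move one way on balance and does not compare them with other genes. The number of arrays limits the precision of each value.

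The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each background, up to 10 genes of positive and 10 of negative ratio with the largest mean ratio among those called and of the same sign on all 4 arrays. The same rule served for the mean and the difference, where up to 5 places per direction were filled by the smallest p. The targeted gene and up to 4 members of each called list were added. Gycbeta100B and foraging (for) were also to be named, but no spot carried either name, and they are not analysed here.

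The deposited ratios are not centred on 0. The median over features was -0.39 for Rover and -0.20 for sitter, and a test against 0 then calls many features of average ratio. Counts against 0 are therefore given also after centring each array on its median. Other alternatives were scaling of the centred arrays, robust moderation, array weights, print lot or replicate number as a block, each background by itself, single spots, a fold threshold of 1.5 and leaving out each array. After the data were seen, 3 alternatives were added: averaging replicates 1 with 2 and 3 with 4, keeping print lot B alone, and keeping the arrays of the lower Cy5 gain.

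The fit was tested on simulated data with the 19325 features and array numbers of the study. The simulated noise was normal and independent between features and arrays, with no shift, probe or dye effect common to arrays. Of features changed by a log2 ratio of 1, it recovered 79% in Rover, 72% in sitter, 76% over both and 42% in the difference, and 4.87%, 4.79%, 4.76% and 7.03% of its calls were false. At a log2 ratio of 0.5 it recovered 15%, 8%, 27% and 2%. The features counted over both included those changed in Rover alone, whose mean over both was smaller than the size named. The false shares hold under the simulated noise and do not carry over to the calls against 0 on the study's arrays. Figures were drawn with matplotlib 3.10.9.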

Results

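Soluble guanylyl cyclase makes the second messenger cGMP, and Gycalpha99B encodes its alpha subunit. The arrays set larvae carrying the DGCalpha1[3] allele of this gene against control larvae in Rover and sitter, natural variants of larval foraging that differ at the gene for a cGMP-dependent protein kinase. The design asks which transcripts differ with the mutation in each background, which do so in both, and whether the response depends on the background. There were 4 arrays per background, and the direction of the ratios is not settled by the labels.

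The spots named for Gycalpha99B itself did not separate the mutant from its control. Its mean log2 ratio was -0.26 ± 0.66 (SD, n = 4) in Rover and -0.27 ± 0.31 (SD, n = 4) in sitter, with limma adjusted p of 0.396 and 0.451. The spots disagreed in sign between arrays, from -1.45 on Rover 2 to 0.51 on Rover 4. After centring, the mean over both backgrounds turned from -0.26 to 0.04. Whether the clone lies in the altered part of the gene is unknown, so these spots check the labels only weakly.

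On all 8 arrays most spots had a negative ratio. Array medians ran from -0.10 on sitter 1 to -0.47 on Rover 3, and positive ratios made up 22.4% to 36.3% of the spots. The negative side was long: the 5th percentile lay between -1.51 and -1.80 on the 5 arrays scanned at a Cy5 gain of 64, and between -0.81 and -1.06 on the 3 arrays at 67 or 68. Neighbouring spots, which are known or probable duplicates, correlated at 0.63 to 0.76 within an array.

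**Figure D1:**
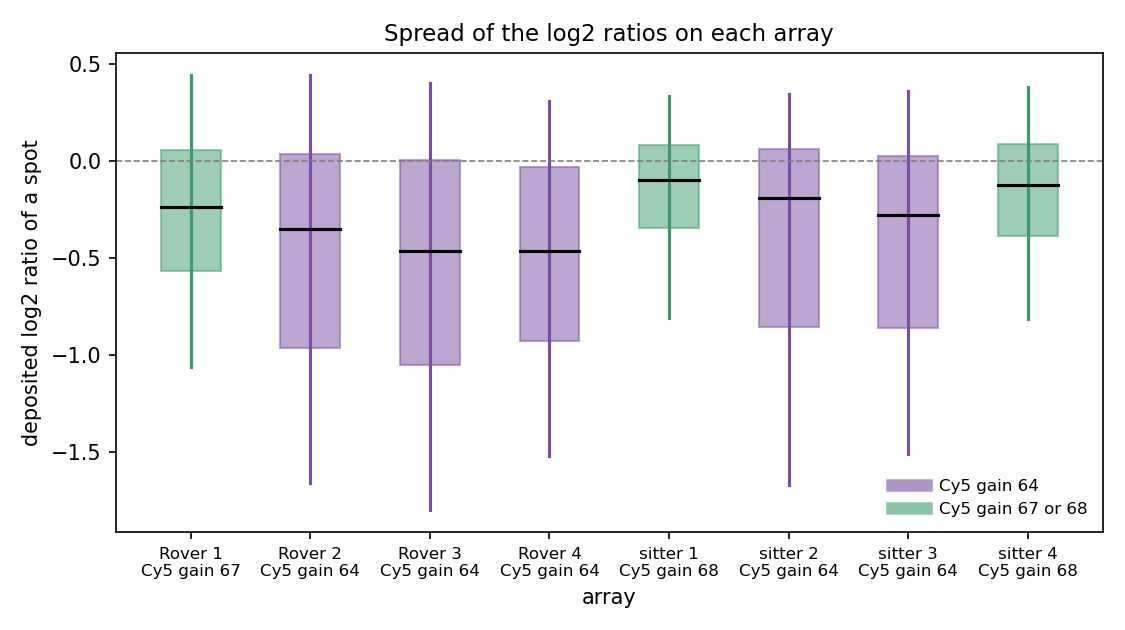
Deposited log2 ratio of the 27648 spots (vertical axis) on each of the 8 arrays (horizontal axis). Boxes span the 25th to 75th percentile, black lines are medians and vertical lines run from the 5th to the 95th percentile; the medians lie between -0.10 and -0.47, and the 5 arrays at a Cy5 gain of 64 reach lowest.

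In Rover the largest ratio belonged to CG11911, at -3.96 ± 0.35 (SD, n = 4; adjusted p = 1.21e-05), negative on all 4 arrays. Next among the negative genes were CG12693 at -2.17, the cytochrome P450 genes Cyp6a23 at -2.16 and Cyp6a14 at -2.07, CG6277 at -2.14, the salivary glue gene Sgs4 at -2.06 and CG6283 at -2.04. CG3330 stood at -2.02, CG10064 at -1.92 and Adgf-B, of the adenosine deaminase-related growth factor family, at -1.84. On the positive side CG10910 led with 2.51 ± 0.89 (SD, n = 4; adjusted p = 0.00198). It was followed by the glutathione S-transferase gene GstE3 at 1.42, the aspartyl protease gene Bace at 1.41, the cadherin gene Cad96Cb at 1.29, the lysyl oxidase-like gene Loxl1 at 1.28 and the prophenoloxidase gene PPO3 at 1.27. CG2065 (1.26), CG3355 (1.25), CG3842 (1.19) and CG14302 (1.07) completed the positive genes.

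Spread between the Rover arrays was uneven among these genes. PPO3 varied by an SD of 0.16 and CG11911 by 0.35, whereas CG6283 varied by 1.96, CG6277 by 1.72, CG12693 by 1.63, Adgf-B by 1.60 and Sgs4 by 1.60. The means of CG12693, CG10064 and Adgf-B went to -1.42, -1.18 and -1.06 without Rover replicate 4, and that of CG3330 to -1.33 without Rover replicate 3, each still called. Bace, CG2065, CG6277 and CG6283 did not pass without Rover replicate 1 or without Rover replicate 2. For Sgs4 the arrays gave -3.15, -3.71, -0.82 and -0.56. CG6283 lost its call after centring (adjusted p = 0.0506), and the other 19 genes named for Rover kept theirs.

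In all, limma called 9019 of the 19325 features in Rover, 328 positive and 8691 negative, and among the 6793 genes 117 positive and 3036 negative. After centring the count was 9304, now 4780 positive and 4524 negative (1709 and 1442 among the genes), and 4852 features were called both ways. The positive share of calls was thus 3.64% as deposited and 51.4% centred, so the balance of signs depended on the centring.

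Genes of larval storage and fat body proteins had ratios in Rover above those of other genes. The mean of the 10 measured members exceeded that of other genes by 0.55 (camera adjusted p = 0.0299; adjusted p = 0.91 with an estimated correlation; 0.251 after centring). Of the members, 0 were called positive, 1 was called negative and 9 did not pass, the same numbers as when adjusted over the list alone; after centring 4 were positive, 1 negative and 5 did not pass. The called member was the yolk protein gene Yp2 at -0.90, while the fat body gene Fbp2 stood at 1.54 ± 1.63 (SD, n = 4; adjusted p = 0.122), Yp3 at 0.33 and Mtp at -0.31. The 20 genes of glycolysis and central carbon metabolism also lay above the others, by 0.35 (camera adjusted p = 0.0299; adjusted p = 0.91 with an estimated correlation; 0.0103 after centring). Their median ratio was -0.05, against -0.34 for all genes. The hexokinase gene Hex-C, at -0.81, was the 1 called member, also when adjusted over the list alone. After centring Hex-C did not pass (adjusted p = 0.0603), and 9 members were called positive, 0 negative and 11 not. As deposited, Tps1 (-0.31), Glys (-0.23) and Ald1 (-0.27) did not pass.

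In sitter CG9360 had the largest ratio, -2.45 ± 0.27 (SD, n = 4; adjusted p = 0.000937). The limostatin gene Lst, for a peptide hormone, stood at -2.02 and the ionotropic receptor gene Ir93a at -1.97, followed by CG11893 at -1.80, wda at -1.67, CG7720 at -1.59, the cytochrome P450 gene Cyp312a1 at -1.58, CG13318 at -1.53, CG14864 at -1.48 and the cuticle protein gene Ccp84Ab at -1.36. The positive genes were led by tw, an O-mannosyltransferase gene, at 2.01 ± 0.25 (SD, n = 4; adjusted p = 0.0116). CG10560 followed at 1.57, CG3251 at 1.52, the antifungal peptide gene Drs at 1.49, Bace at 1.28, the topoisomerase gene Top3alpha at 1.20 and CG14302 at 1.16. Drsl5, a relative of Drs, stood at 1.15, CG15043 at 1.03 and the septate junction gene Ssk at 0.96.

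The sitter means of wda and CG14864 rested largely on a single array. The value of wda was -3.84 on sitter 2 and -0.75 to -1.07 on the other arrays, and without sitter replicate 2 the means were -0.95 (adjusted p = 0.0743) for wda and -0.89 (0.0932) for CG14864. After centring wda (adjusted p = 0.0515) and Cyp312a1 (0.0542) did not pass.

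limma called 4583 features in sitter, 140 positive and 4443 negative, and among the genes 64 positive and 1371 negative. The count fell to 2573 after centring (522 positive, 2051 negative; 213 and 585 among the genes), and the positive share moved from 3.05% to 20.3%. With the arrays also scaled to a common spread it was 6870, with 2444 positive and 4426 negative. It was 24 without sitter replicate 2 and 22 without sitter replicate 3, the arrays of this background scanned at the lower Cy5 gain. CG9360, Ir93a, CG10560 and CG3251 stayed called without either array, with adjusted p for CG9360 of 0.00824 and 0.0148.

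Chemosensory genes had the smallest adjusted p of the 21 lists in sitter. Of 26 measured members 13 were called negative, 0 positive and 13 did not pass, and 19 were negative when adjusted over the list alone; after centring 10 were negative and 0 positive. Their mean lay below that of other genes by a log2 difference of -0.41 (camera adjusted p = 0.00359; adjusted p = 0.995 with an estimated correlation; 0.000335 after centring). In Rover 20 members were called negative and 0 positive, 13 and 0 after centring (camera adjusted p = 0.0714; 0.0103 after centring), and the difference between backgrounds had a camera adjusted p of 0.712. Besides Ir93a, the odorant-binding protein genes Obp56e (-0.99), Obp57c (-0.94) and Obp47a (-0.84) had negative ratios. Detoxification genes, the cytochrome P450, glutathione S-transferase and UDP-glycosyltransferase families, had 46 of 108 members negative, 0 positive and 62 not passing; adjusted over the list alone, 52 were negative and 1 positive. After centring 20 were negative, 2 positive and 86 did not pass. Their mean differed from that of other genes by -0.18 (camera adjusted p = 0.00996; adjusted p = 0.995 with an estimated correlation; 0.00118 after centring). Examples were Cyp6a8 at -1.26, Cyp6a18 at -0.80, Cyp310a1 at -0.65 and Cyp12c1 at -0.63. Signal over background was not available, so it could not be checked whether dim spots enter the results of any list.

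Over both backgrounds the positive genes were CG10910 at 1.64, Bace at 1.35, CG10560 at 1.17, CG14302 at 1.12, CG5550 at 0.98, GstE3 at 0.85, CG30059 at 0.83, pst at 0.78, Drsl5 at 0.75 and the tetraspanin gene Tsp42Ec at 0.74. Of these, Bace, CG10560, CG14302, pst and Tsp42Ec were called in Rover and in sitter separately. The ratio of CG14302 was 1.07 ± 0.32 (SD, n = 4) in Rover and 1.16 ± 0.24 (SD, n = 4) in sitter, and that of Tsp42Ec 0.76 ± 0.27 and 0.71 ± 0.09. The negative genes were CG11893 at -1.82, Cyp312a1 at -1.59, CG12693 at -1.48, CG7720 at -1.47, CG13318 at -1.45, CG18467 and CG1958 at -1.38 each, Phlpp at -1.37, CG6283 at -1.37 and CG15111 at -1.36. Of these, CG11893, Cyp312a1, CG7720, CG13318 and CG1958 were called in Rover and in sitter separately. CG12693, CG18467, CG6283 and CG15111 were called in Rover alone (adjusted p in sitter of 0.291, 0.0583, 0.459 and 0.0877). Phlpp was called in neither (adjusted p = 0.14 in Rover and 0.0649 in sitter). Phlpp was at -4.42 on sitter 2 and between -0.38 and -0.94 on the other sitter arrays, its mean over both going to -0.91 without sitter replicate 2. CG30059 did not pass without Rover replicate 3 (adjusted p = 0.0862), Rover replicate 4 (0.0585) or sitter replicate 3 (0.0542). CG6283 missed the threshold after centring (adjusted p = 0.0559). It also did not pass without Rover replicate 1 or 2 or without sitter replicate 2 or 3 (adjusted p of 0.0553 to 0.0634).

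limma called 9436 features over both backgrounds, 398 positive and 9038 negative. Centred, it called 11611, with 5424 positive and 6187 negative, of which 6585 were among the 9436; the positive share was 4.22% as deposited and 46.7% centred. Chemosensory genes were again negative, 19 of 26 by the test over all features and 20 when adjusted over the list alone, with 0 positive, and centred 17 were negative and 1 positive (camera adjusted p = 0.0294; adjusted p = 0.993 with an estimated correlation; 0.00197 after centring). The odorant-binding protein gene lush stood at -1.13, Ir93a at -1.34, Obp57c at -1.07 and Obp56e at -0.90.

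The backgrounds ran together across features, with a Pearson r of 0.76 and a Spearman rho of 0.787 between the mean ratios of the 19325 features, which are not independent replicates. Single arrays of different backgrounds correlated at 0.312 to 0.637 (median 0.48), which overlapped the values for arrays of the same background, 0.413 to 0.599 in Rover and 0.372 to 0.667 in sitter. Of the 117 positive genes in Rover and 64 in sitter, 20 were shared, against 1.1 for independent lists. Of the 3036 and 1371 negative genes 1300 were shared, against 613. After centring 168 positive genes were shared against 53.6, and 478 negative genes against 124. Opposite signs were called for 10 genes, against 52.2 for independent lists, and for 6 against 192 after centring. No RNA is stated to be shared by the backgrounds, but probe, dye and print effects are common to all arrays and enter each of these numbers.

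Among the genes that passed the test of the difference, CG11911 and CG9360 differed most between backgrounds. CG11911 was at -3.96 in Rover and 0.19 ± 0.22 (SD, n = 4) in sitter, a difference of -4.15 ± 0.21 (SE; adjusted p = 0.000176). CG9360 went the other way, with 0.65 ± 0.43 (SD, n = 4) in Rover and -2.45 in sitter, a difference of 3.10 ± 0.24 (SE; adjusted p = 0.00154). The cathepsin gene CtsL2 was at -1.18 in Rover and 0.11 in sitter (difference -1.29, adjusted p = 0.0396), and Rab26, for a small GTPase, at -1.01 and 0.20 (difference -1.21, adjusted p = 0.0437). For all 4 genes the arrays of the backgrounds did not overlap, which the naming rule required for the difference. With print lot as a block Rab26 did not pass (adjusted p = 0.0634). CtsL2 and Rab26 did not pass after centring (adjusted p = 0.0527 and 0.083), whereas CG11911 (8.78e-05) and CG9360 (0.000844) did. CtsL2 and Rab26 also did not pass with any single array left out (adjusted p of 0.0515 to 0.217). After centring and scaling together CG11911 did not pass (adjusted p = 0.0584).

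**Figure D2:**
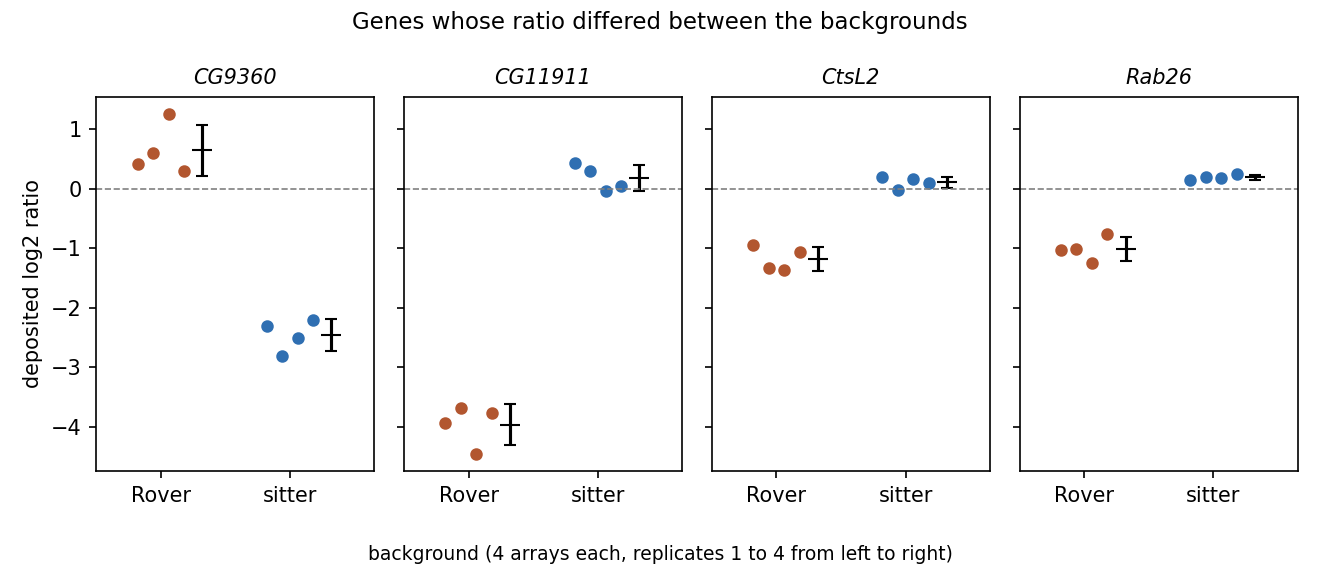
Deposited log2 ratio (vertical axis) of CG9360, CG11911, CtsL2 and Rab26 on the 4 arrays of each background (horizontal axis). Points are arrays, and black marks are the mean with its SD; CG9360 lies near 0.65 in Rover and -2.45 in sitter, and CG11911 near -3.96 and 0.19.

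No other named gene passed in the difference. The remaining places of the naming rule, 5 per direction, went to CG7382 (1.21, adjusted p = 0.0584), the glutamine synthetase gene Gs1 (1.16, 0.0865), the alkaline phosphatase gene Alp7 (1.31, 0.0966) and the peroxiredoxin gene Prx6c (1.71, 0.102) on the positive side, and Cyp6a14 (-1.83, 0.065) and CG6357 (-1.64, 0.0653) on the negative. Of the genes named for sitter, CG3251 (-1.38, 0.0708) and tw (-2.39, 0.0988) did not pass either. After centring CG7382 (adjusted p = 0.025), Prx6c (0.025), Alp7 (0.0365) and PPO2 (0.0438) passed. limma called 9 features in all, 4 positive and 5 negative, 4 of them named genes, against 1816 features at an unadjusted p under 0.05. The centred count was 15, with 12 positive and 3 negative, so the positive share moved from 44.4% to 80%. With only the arrays at the lower Cy5 gain, 3 of Rover and 2 of sitter, limma called 0 features (1313 at an unadjusted p under 0.05), while the differences of CG11911 (-4.10, adjusted p = 0.0532) and CG9360 (3.38, 0.0949) kept their size.

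Storage and fat body genes differed most among the lists, Rover lying above sitter by 0.89 relative to other genes (camera adjusted p = 1.81e-05; adjusted p = 0.219 with an estimated correlation; 0.00251 after centring). No member was called by itself by limma, also when adjusted over the list alone, and 3 of 10 had an unadjusted p under 0.05. Over all 6793 genes, 777 had an unadjusted limma p under 0.05 in the difference. Fbp2 differed by 2.94, the larval serum protein gene Lsp2 by 2.10, Fbp1 by 1.25 and apolpp, for a lipid carrier, by 0.48. Glycolysis and central carbon genes differed by 0.32 (camera adjusted p = 1.81e-05; adjusted p = 0.534 with an estimated correlation; 5.1e-05 after centring), with 0 of 20 members called and 1 at an unadjusted p under 0.05. Their members of smallest p were Glyp at 0.57, Eno at 0.41, Pgi at 0.36 and fbp at 0.24. Midgut digestive enzymes differed by 0.19 (camera adjusted p = 0.028; adjusted p = 0.721 with an estimated correlation; 0.148 after centring), with 0 of 24 called and 1 at an unadjusted p under 0.05. Jon99Fii (0.39) and Jon65Ai (0.26) were positive there, and Mal-A2 (-0.51) and Mal-A3 (-0.49) negative. For the glycolysis and midgut lists the share of members at an unadjusted p under 0.05 was below that over all genes.

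Single arrays of a background disagreed on the storage genes and on genes of the salivary glue list. Fbp2 was at 3.78 on Rover 3 and 0.12 on Rover 1, and at -0.02 on sitter 1 and -4.27 on sitter 4. Lsp2 ran from -0.39 to 1.75 in Rover and from -0.24 to -3.84 in sitter. Eig71Ee was at 3.63 on Rover 3 and 4.75 on Rover 4, at -0.38 and -0.24 on the other Rover arrays, and at -5.03 on sitter 3.

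**Figure D3:**
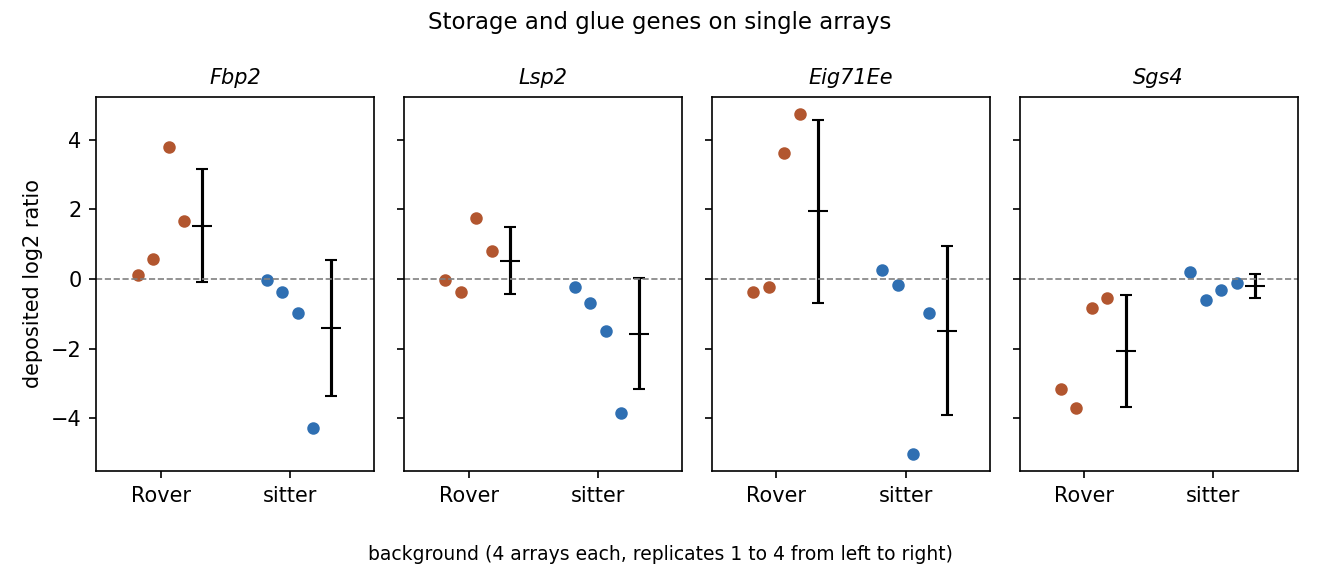
Deposited log2 ratio (vertical axis) of Fbp2, Lsp2, Eig71Ee and Sgs4 on the 4 arrays of each background (horizontal axis), with the mean and SD in black. Values of a gene differ between arrays of the same background by up to several log2 units, as for Eig71Ee between 4.75 on Rover 4 and -0.38 on Rover 1.

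The list of cGMP signalling genes, closest to the mutated gene, did not stand apart from other genes. In Rover 8 of 15 members were called negative and 0 positive (camera adjusted p = 0.416), in sitter 4 and 0 (0.637; centred 3 and 0), and in the difference 0 of 15 passed in limma, with 3 at an unadjusted p under 0.05 (0.712). The largest ratios in Rover were those of CG10738 at -1.80, of the guanylyl cyclase gene Gyc88E at -1.08 and of the phosphodiesterase gene Pde1c at -1.06. After centring 5 of the 15 were negative and 1 positive in Rover. The cAMP signalling list gave camera adjusted p of 0.904 in Rover, 0.812 in sitter and 0.712 in the difference, and the list of neuronal genes 0.6, 0.812 and 0.159. Genes of feeding peptides and the insulin pathway gave 0.6, 0.966 and 0.679.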

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

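In this part the tests of scanner gain, larval age, spot noise and print lot were chosen after the results they bear on were seen. So was the count of splits by print lot. Those of spot noise and print lot replaced earlier tests taken to decide nothing, for spot noise the SD of duplicate spots against that between arrays. The glue genes in sitter were set apart once their values were known. The sign patterns, the splits of the arrays and the comparison of clones were set earlier.

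A difference between the backgrounds set apart CG11911 (Rover minus sitter, -4.15), CG9360 (3.10), CtsL2 (-1.29) and Rab26 (-1.21). Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many as 9 features, and the highest of the others called 1. Chance can be excluded for this count only if any array could have stood in either group and each array held separate RNA. The labels do not state the latter. Of the 20 splits that, like the real one, keep an array of print lot A in each group, 1 called 9 and the highest other 0, which is too few splits for a share under 0.05. The count was 11 with print lot as a block and 0 with replicates averaged in pairs (limma, 1729 at an unadjusted p under 0.05). The difference of the gene lists was not of this kind. Larval storage and fat body genes (0.89), glycolysis and central carbon genes (0.315) and midgut digestive enzymes (0.193) lay higher in Rover relative to other genes, but 13 of the 35 splits called at least 3 lists. The highest of the others called 6, with Rover 1 grouped with sitter 2, 3 and 4, so chance cannot be excluded for the lists.

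For the tests against 0, the arrays' signs were turned in place of regrouping. The 4 arrays of a background allow 8 sign patterns, too few for a share under 0.05: 1 of 8 gave as many calls in Rover (9019 features, highest other 0) and 1 of 8 in sitter (4583, highest other 0). Over both backgrounds 1 of 100 patterns drawn gave as many as 9436, the highest other giving 7683, so chance signs can be excluded there. A shift common to all arrays gives the same outcome whether it comes from the larvae or from the slides.

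The many negative ratios on all arrays may owe part of their size to the gain of the Cy5 detector. The mean 5th percentile was -1.63 ± 0.12 (SD, n = 5) at a gain of 64 and -0.895 ± 0.14 (SD, n = 3) at 67 or 68, with no overlap (one-sided exact permutation p = 0.0179, the smallest that 56 splits allow). Within print lot B the single array at the higher gain also lay above the 5 others, where the smallest p possible is 0.167. A change of the transcripts in the mutant predicts that 2 clones of a gene share their ratio, and over 687 genes these correlated at 0.345 (95% interval 0.278 to 0.409), against 0.934 for duplicate spots; this falls between the values set for and against it, so a part of each explanation stays open. For RpL32, a ribosomal protein gene, the mean ratios of 10 clones ran from -1.02 to -0.0034, and for the chaperone gene DnaJ-1 those of 8 clones from -1.49 to -0.03.

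Storage and glue genes differed in ratio between arrays of the same background, some of them in sign. Relative to all genes, the mean of the storage list ran from 0.136 to 1.07 in Rover and from 0.0333 to -1.04 in sitter. The mean of the glue list ran from -0.868 to 0.56 in Rover. Such differences may reflect larvae of different developmental age behind the paired RNAs. The mean of the storage list in both backgrounds and of the glue list in Rover varied between arrays more than 95% of 10000 random lists. This held also without the most variable member (3 of 3). Independent noise that is larger in these genes would do the same, so random lists do not decide on noise of single spots. Over the 17 genes of both lists duplicate spots had an SD of 0.305, against 0.971 between arrays of a background. Pooled over these genes, noise that differs between duplicates was thus the smaller part. The pooled SD between arrays takes in large values such as those of Eig71Ee (2.53), Fbp2 (1.8) and Lsp2 (1.32). It therefore does not decide on noise in the other members. In sitter the glue list fell to a percentile of 20.7 without Eig71Ee, so its excess rested on this gene. The duplicate SD of Eig71Ee was 0.136, against 2.42 between sitter arrays, and noise stays open for the other glue genes there. Spread beyond that of random lists was not particular to these genes. Of the 21 lists, 5 lay above the 95th percentile in both backgrounds, among them detoxification, oxidative phosphorylation and muscle sarcomere. Within print lot B alone the spread was above 95% of random lists in 4 of 4 pairs of list and background, which argues against the print lot as the whole cause, although replicate 1 lay outside the range of lot B in 3 of 4. Larval age stays open. With the ecdysone response list included, 4 of 6 pairs of list and background lay above the 95th percentile of random lists. Among these was the glue list in sitter, whose excess rested on Eig71Ee. The ecdysone response list was at a percentile of 27.2 in Rover and 14.9 in sitter. A list mean does not show members that move in opposite directions, so this low spread does not decide on age. The glue list also held Sgsh, a sulphohydrolase gene taken in by its name.

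Single arrays far from the other 3 of their background were found in 10 of 208 groups tested, or 4.81%, about the 5% that chance gives. GstE3 was at 0.83 on sitter 3 and at 0.01 to 0.13 on the other sitter arrays. Cad96Cb reached 2.22 on Rover 3 against 0.88 to 1.09. Drs was at -1.24 on Rover 3 and between 1.23 and 1.46 on the other Rover arrays. On sitter 2, wda was at -3.84 and Phlpp at -4.42. Cyp312a1 was at -2.95 on Rover 1, where the others lay between -1.33 and -1.02, and CG14864 was at -0.34 there, where the others lay between -1.26 and -1.22. CG5550 was at 2.03 on sitter 3 against 0.45 to 0.68. On sitter 4, Cyp6a8 was at -0.749 against -1.49 to -1.37, and the enolase gene Eno was at -0.878 against -0.19 to -0.06.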

How the results depend on the processing

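The averaging of replicates in pairs, the use of print lot B alone and the use of arrays at the lower Cy5 gain were chosen after the data were seen. No named result that was called changed sign under any alternative, whereas centring turned the sign of 274 of the 9019 features called in Rover and 345 of the 9436 called over both backgrounds, of which 0 were called after it (limma). The counts for Rover and for both backgrounds stayed within 1.5 times, although only 4852 of 9304 features called after centring in Rover were among the 9019 called as deposited. The cause of each change below was not tested.

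The sitter count of 4583 became 2573 after centring, 2433 with print lot as a block and 2648 with the background fitted by itself. Leaving out single arrays gave 22 to 5023, with 24 without sitter replicate 2 and 22 without sitter replicate 3, all of them among the 4583. For Rover the range was 7090 to 8918, and for both backgrounds 8450 to 9514. The difference count of 9 became 15 after centring, 1 after centring and scaling together, 17 with every spot taken by itself, and 0 with replicates averaged in pairs (limma, 1729 at an unadjusted p under 0.05) or with the lower Cy5 gain alone (1313); leaving out arrays gave 6 to 8. The called lists, 2 in Rover, 2 in sitter, 1 over both and 3 in the difference, became 0 in each with an estimated correlation. By fry, which tests a list against no change and so takes in the shift of all genes, 17, 9, 21 and 0 were called, which says nothing on lists standing apart. Centring gave 2 lists over both. Leaving out arrays gave 1 to 4 lists in Rover, 2 to 3 in sitter, 1 to 3 over both and 2 to 4 in the difference, the 1 in Rover being without Rover replicate 2 and the 4 without Rover replicate 4. The correlation of the backgrounds was 0.706 to 0.766 when arrays were left out.

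Of the genes named for the difference, CG11911 lost its call in 3 of 20 alternatives, CG9360 in 2, CtsL2 in 15 and Rab26 in 16. In every alternative run, 14 of 22 called Rover results, 4 of 27 for sitter and 20 of 24 over both kept their call. With the replicate number as a block (replicate block) the counts were 9230, 5854, 9507 and 7, and CtsL2 (adjusted p = 0.134) and Rab26 (0.174) were lost. Same-numbered arrays deviated together at correlations of 0.29, 0.18, 0.025 and 0.12, and not every array matched its own number best, so the numbers were not taken to pair the samples. Filters on missing values changed nothing, as 0 values were missing. Apart from the sign patterns above, turning an array's sign was not run as an alternative, as no array pair correlated below 0. Effects common to all arrays could also bring that about. Signal over background is not part of the table, so dim spots could not be left out.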

Other observations

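The descriptions of single genes in the next paragraph were chosen after their values were seen; the linkage tests were set before.

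Immune and blood cell genes moved in several directions. In the antimicrobial and immune list Drs (1.49) and Drsl5 (1.15) were positive in sitter and 1 of 11 members was negative (0 after centring), while in Rover 5 were negative, among them TotF at -1.43 and TotB at -1.04, and 0 were positive (camera adjusted p = 0.637 in sitter and 0.529 in Rover). After centring the balance in Rover turned to 4 positive and 2 negative members, with Drs (limma adjusted p = 0.0439) and Drsl5 (0.0145) among the positive. As deposited, Drs was at 0.68 in Rover (adjusted p = 0.213), with -1.24 on Rover 3 and 1.23 to 1.46 on the other Rover arrays. Drsl5 was at 0.35 there (0.147). Neither gene passed in the difference between backgrounds (adjusted p = 0.653 for Drs and 0.41 for Drsl5). Of 11 haemocyte genes, PPO3 (1.27) and PPO2 (0.41) were positive in Rover and 5 were negative, with vkg at -0.95, eater at -0.88 and Hml at -0.81 (camera adjusted p = 0.588). In sitter 4 of the 11 were negative and 0 positive, and 1 and 0 after centring (camera adjusted p = 0.637). PPO2 was called there with the opposite sign, at -0.55 (adjusted p = 0.0181; 0.0595 after centring). After centring 2 haemocyte genes were positive and 2 negative in Rover. Genes of cytosolic ribosomal proteins (camera adjusted p = 0.166 in Rover, 0.0932 in sitter), oxidative phosphorylation (0.0874, 0.302), cuticle (0.894, 0.682), muscle sarcomere (0.494, 0.851), lipid metabolism (0.529, 0.682), heat shock (0.6, 0.637), testis (0.643, 0.851) and proliferation (0.889, 0.991) did not pass.

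Among genes with close duplicate spots, the alpha-mannosidase genes LManV and LManVI differed widely between arrays of the same background. LManVI was at -3.56 and -3.16 on Rover 1 and Rover 2, at 1.74 and 1.66 on Rover 3 and Rover 4, and at -4.09 on sitter 3. LManV was at -3.38, -2.19, 1.44 and 1.79 on the Rover arrays and at -3.75 on sitter 3. CG1850 and FucTB were, like Fbp2, lowest on sitter 4 and highest on Rover 3, at -5.75 and -3.56 on sitter 4 and at 3.26 and 3.66 on Rover 3. The globin gene glob1 ran the other way, with 1.22 and 1.18 on Rover 1 and Rover 2 and -1.67 on Rover 3. Over the 30 genes that varied most, Rover 1 and Rover 2 correlated at 0.96 and Rover 3 and Rover 4 at 0.76 across genes, against 0.035 to 0.11 between these pairs. Across backgrounds, sitter 2 correlated at 0.78 with Rover 1 and at 0.71 with Rover 2. These genes were picked for their spread, so the correlations only describe them.

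A hypothesis was tested that genes near Gycalpha99B carry chromosome differences brought in with the mutant allele, which could give ratios in both backgrounds or large negative ratios in a single background. Among the 100 measured genes nearest to it in gene order, 1 (Cap-D2) was called positive over both backgrounds, or 1%, against 2.39% of 6599 other genes (one-sided Fisher's exact p = 0.911). For centred ratios of at least 1.5-fold to the negative side called in a single background, 4 of 100 lay near against 9.9% elsewhere (one-sided Fisher's exact p = 0.991). The exact 95% interval of the share near the gene reached 5.45% for the positive ratios, 2.27 times the share elsewhere, so a modest excess there cannot be ruled out. For the large negative ratios it reached 9.93%, about the share elsewhere, which argues against an excess near the gene for these ratios. As 653 such genes lay elsewhere, linkage to 100 near genes could not have been their main source at any outcome. Negative calls over both and large positive ratios in a single background were not tested, although the direction of the ratios is not settled.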
